A study of Mus musculus with 6 samples.

How the data were processed

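RNA of whole mouse kidneys was sequenced from poly(A)-selected, strand-marked libraries, 3 from control mice and 3 from mice with diabetic kidney disease (DKD). The labels give the group and the replicate number of each library. They do not name the strain, the way diabetes was induced, the age or the day of collection, and they do not state outright that each library is a separate animal. The p-values therefore measure the spread between these 6 libraries, which may in part be technical.

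The authors deposited one table of raw read counts per gene, with no normalisation, for 55401 Ensembl gene IDs. Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used with the GRCm39 build. The version, order and role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here. Gene symbols were taken from a table of the reference, which is of another build (GRCm38). That reference served only for symbols and for the order of neighbouring genes, and no coordinates are printed. A symbol was found for 55141 IDs, and 25471 IDs had no count in any library. IDs that share a symbol with another ID number 107. The IDs without a symbol held at most 0.00963% of the counts of a library.

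Library totals ran from 64816622 to 77417638 counts. A gene with no count in a library could still be present at up to 3 counts, which is 0.0353 to 0.0505 CPM (the unit of normalised counts, scaled to the size of each library) in these libraries. This floor covers counting error only, because the counts are of reads without molecular identifiers. Reads shared between near-identical genes can be split in ways the table does not show. The predicted genes Gm10925, Gm28437 and Gm28661, which resemble mitochondrial genes, held 2.33% to 2.69% of the counts together.

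Counts were analysed in R 4.3.3. The test fixed before the data were examined was the quasi-likelihood test of edgeR 4.0.16 (robust, two-sided) on the deposited counts, with TMM factors, the default low count filter on the groups, and Benjamini-Hochberg adjustment over the 19197 genes tested, with a threshold of 0.05. CPM values are scaled by the TMM factors. Standard errors of log2 fold changes come from the same test statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over 37 lists. Those lists were also fixed before the data were examined. They hold 779 genes, of which 730 were tested and 37 stand in more than 1 list. Of their members, 2 were matched through an older symbol.

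The rule for named genes was fixed at the same time. It took Setdb2 and Smad3, the 12 largest changes in each direction among genes past the threshold with a mean CPM of at least 1 and no overlap between groups, every histone methyltransferase past the threshold over all genes or over the list alone, and up to 4 members of each list with the smallest p-values. Since the edgeR test called no gene, the part on the largest changes gave none. It was then applied to limma-voom with sample quality weights, a choice made after seeing the data. Of the list members that the rule takes, examples are printed, and a further gene that it takes is not reported here. Genes named outside the rule were chosen after their values were seen.

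Alternatives planned before the data were examined were RLE and upper quartile factors, library size alone, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of CPM 1 in 3 libraries, leaving out the 50 most counted genes, glmTreat against 1.5-fold, a fit that was not robust, a block on the replicate number, and leaving out each library. For the lists, an estimated correlation and fry were planned. Alternatives chosen after seeing the data were limma-voom without weights, weighted limma-voom and DESeq2 on fewer libraries, the weighted fit on other splits of the libraries, camera with quality weights, 2 more scalings for the lists, a list of 36 hepatocyte genes and a list of 25 p53 target genes.

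The tests were tried on simulated counts for the DKD against control comparison, over 18691 genes. The edgeR test recovered 1.52% of genes changed 1.5-fold, 26.6% of those changed 2-fold and 71.4% of those changed 4-fold, with 7 false calls. Weighted limma-voom recovered 1.52%, 25.0% and 65.1% with 8 false calls. No simulated library was set apart from the rest of its group, unlike DKD replicate 1 in the data. The false calls of each test here therefore do not measure those in the data, above all for the weighted fit. DESeq2 recovered 10.6%, 45.3% and 77.8%, which is 7, 29 and 49 genes, with 66 false calls. That share of false calls is far more than its adjusted threshold is meant to allow. Counts of genes called by DESeq2 in the data are therefore weak evidence. Camera called 0 of 36 lists simulated without a change. The simulated genes varied independently of each other, so this could not show how often camera calls lists of correlated genes. In the data the estimated correlation within a list reached 0.858, for nuclear genes of oxidative phosphorylation. No library matched another within sampling noise: the chi-square per degree of freedom was 29.6 or more for every pair.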

Results

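The series profiled gene expression in whole kidneys of mice with diabetic kidney disease (DKD), with histone methyltransferases as its stated subject, and its title names Setdb2, Smad3 and podocytes. Read counts were compared between 3 control and 3 DKD kidneys. Total counts were 64816622, 68906395 and 72845799 in control replicates 1 to 3, and 77417638, 71588579 and 77161106 in DKD replicates 1 to 3. The libraries did not fall cleanly into the groups. The first principal component (44.4% of the variance) set DKD replicates 2 and 3 apart from the other libraries, and the second (21.0%) set DKD replicate 1 apart. The median correlation of DKD replicate 1 with the other DKD libraries was 0.943, against 0.960 with the controls. DKD replicate 1 also held 2321 CPM of Alb, the albumin transcript made mainly by the liver and named here after its values were seen, where the other libraries held 7.20 to 14.7 CPM.

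The comparison of DKD with control kidneys over all genes asked which transcripts differ in the diseased kidney. With the quasi-likelihood test of edgeR, 0 of 19197 genes passed an adjusted p of 0.05. The smallest adjusted p was 0.0721, for Cyp2d9, a cytochrome P450 gene named here after its values were seen, at 388 ± 50.2 CPM in control and 131 ± 3.73 CPM in DKD kidneys (SD, n = 3). At an unadjusted p under 0.05 there were 3694 genes, 2340 higher and 1354 lower in DKD, where chance would give 960 on average. Genes that vary together can move such a count far from that average. The other splits of the libraries, 3 against 3, gave 182 to 2062 genes. Other tools gave very different counts. DESeq2 called 1749 genes (1195 higher, 554 lower). Limma-voom called 3401 with sample quality weights (1907 higher, 1494 lower) and 1 without weights. Calls of DESeq2, here and below, need caution, since it made 66 false calls on simulated counts where edgeR made 7. The edgeR test without DKD replicate 1 called 3101 genes (1933 higher, 1168 lower). It called 7 genes without control replicate 1, 1 without DKD replicate 3 and 0 without each of the others. The weighted count also rested on single libraries, with 0 genes without control replicate 2, control replicate 3, DKD replicate 2 or DKD replicate 3. CPM values of the groups did not overlap for 4870 genes (25.4%), where chance gives 10% on average.

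Histone methyltransferases, the enzymes that place methyl groups on histones, were not shifted to one side as a group. Of 52 listed genes 48 were tested, 27 with a higher and 21 with a lower fitted level in DKD, and 42 lay within 0.5 of 0 on the log2 scale. None passed the threshold over all genes with edgeR, where the smallest adjusted p was 0.103. Adjusted over the list alone, 2 rose: Setd7, a lysine methyltransferase, by 0.99 ± 0.17 (log2, SE) from 14.5 ± 1.88 to 28.6 ± 5.62 CPM (SD, n = 3; adjusted p = 0.0157 in the edgeR model), and Mecom, by 0.71 ± 0.10 from 32.9 ± 1.5 to 53.7 ± 5.27 CPM (adjusted p = 0.00867 in the edgeR model). Both were higher in each DKD kidney than in every control kidney. Ezh2, the catalytic subunit of the Polycomb repressive complex that methylates histone H3, differed by 0.72 ± 0.22 and Prmt2 by 0.51 ± 0.16, with adjusted p of 0.163 and 0.166 over all genes. Over all genes, DESeq2 called 3 list members, weighted limma-voom 5, and edgeR without DKD replicate 1 called 4. Setd7 and Mecom were among the calls of each. These fits reuse the same libraries, so their calls are not independent of each other. The list as a whole was not set apart from other genes by camera (median log2 change 0.04, adjusted p = 0.901), and the direction of that test turned without control replicate 1 (adjusted p = 0.501) and without DKD replicate 1 (adjusted p = 0.897). The mixed test of fry, which asks whether members change in either direction and compares the list with no other genes, gave an adjusted p of 0.00848.

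Setdb2, a methyltransferase of the SETDB family, had CPM values of 8.28, 15.3 and 9.45 in control and 6.62, 9.25 and 8.15 in DKD kidneys. Its log2 difference was -0.46 ± 0.26 (SE; adjusted p = 0.373 with edgeR), so the difference lay within the spread between kidneys. Smad3, which carries the signal of the TGF-beta receptor to the nucleus, had CPM values of 27.1, 30.5 and 34.6 in control and 38.3, 34.6 and 36.5 in DKD kidneys. Its log2 difference was 0.25 ± 0.11 (SE; adjusted p = 0.280 with edgeR) and did not pass the threshold. The values of both genes are of the whole kidney, so they do not show the levels in podocytes.

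**Figure D1:**
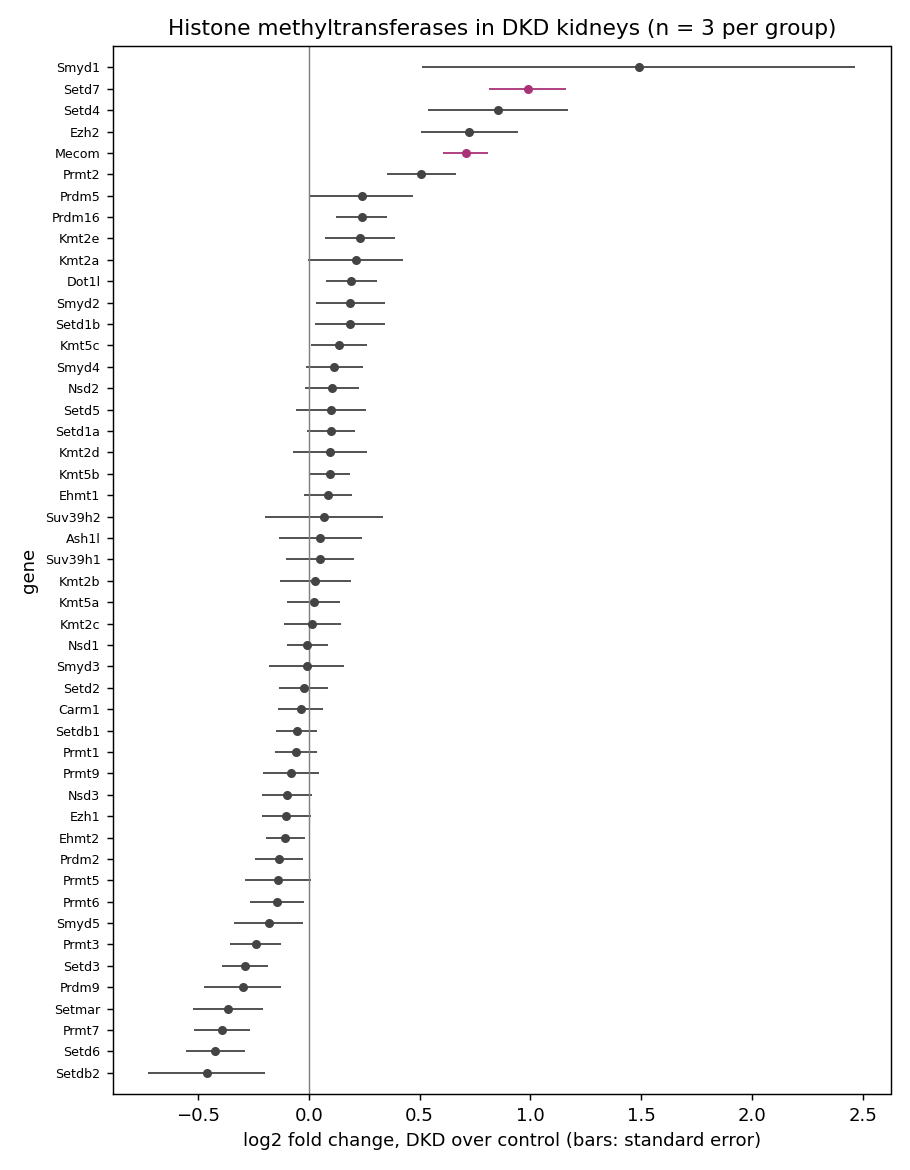
Log2 fold change of each tested histone methyltransferase, DKD over control (horizontal axis, log2; points are edgeR estimates from 3 kidneys per group, bars are standard errors). The coloured points are Setd7 (0.99) and Mecom (0.71), which passed the threshold adjusted over the list alone, and Setdb2 has the lowest estimate at -0.46.

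Gene lists for cell types and processes of the kidney were compared in the same way, and camera set 17 of 37 apart from other genes, 14 higher and 3 lower in DKD. None of these calls held with an estimated correlation, where the adjusted p among them ran from 0.684 to 0.852, and fry called 1 list for a shift in one direction. For changes in either direction fry called 16 of the 37 lists, the histone methyltransferases among them. With edgeR on all 6 libraries no single gene named in the lists passed the threshold over all genes, so each is given as a value. Other fits did call list members over all genes. For example, weighted limma-voom called 22 matrix genes higher and DESeq2, with its many false calls on simulated counts, called 24.

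Extracellular matrix and supporting cell genes were higher in DKD. Of 35 tested matrix genes 34 had a higher fitted level, and 25 rose adjusted over the list alone (median 1.08; camera adjusted p = 1.63e-12; adjusted p = 0.684 with an estimated correlation). Sparc, a collagen-binding matrix protein, differed by 1.54 ± 0.15, Col1a1, a chain of fibrillar collagen, by 1.87 ± 0.25, and Fn1, fibronectin, by 2.12 ± 0.30 (log2, SE). The matrix level of DKD replicate 1 was 0.98 above the control mean, beside 0.90 and 1.28 in the other DKD kidneys. Mesangial and stromal genes had a median of 0.73, with 8 of 18 higher adjusted over the list alone (camera adjusted p = 2.19e-05; adjusted p = 0.684 with an estimated correlation), among them Vim (1.10 ± 0.20) and Postn (2.25 ± 0.42). Podocyte genes had a median of 0.50, with 14 of 25 higher adjusted over the list alone (camera adjusted p = 9.13e-05; adjusted p = 0.684 with an estimated correlation). Examples were Col4a5 (0.96 ± 0.15), a basement membrane collagen, and Nes (1.13 ± 0.24). Endothelial genes had a median of 0.30, with 6 of 18 higher adjusted over the list alone (camera adjusted p = 0.000998; adjusted p = 0.762 with an estimated correlation), including Cdh5 (0.70 ± 0.12) and Nos3 (1.31 ± 0.24). TGF-beta and SMAD signalling genes had a median of 0.29, with 1 of 29 higher adjusted over the list alone, Ltbp3 (1.15 ± 0.18), and Tgfb1 differed by 0.79 ± 0.19. The camera adjusted p was 0.00514, and 0.797 with an estimated correlation. Over all genes, 8 members were called higher by edgeR without DKD replicate 1, 7 by weighted limma-voom and 6 by DESeq2. That last list was not called without control replicate 1 (adjusted p = 0.0643), and its level in DKD replicate 1 was -0.05, inside the controls (-0.14 to 0.11), beside 0.39 and 0.58 in the other DKD kidneys. For mesangial and stromal genes DKD replicate 1 was at 0.26 beside 0.80 and 0.95, for podocyte genes at 0.47 beside 0.47 and 0.81, and for endothelial genes at 0.17 beside 0.28 and 0.48.

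Cell cycle genes were higher in every DKD kidney. All 25 had a higher fitted level and 18 rose adjusted over the list alone (median 1.31; camera adjusted p = 2.19e-12; adjusted p = 0.684 with an estimated correlation; adjusted p = 0.0476 with fry). Cdk1, the kinase that drives entry into mitosis, differed by 1.91 ± 0.27, Top2a, a topoisomerase of dividing cells, by 1.74 ± 0.27, and Mcm3, part of the replicative helicase, by 1.43 ± 0.21 (log2, SE). The list level was 1.62 above the control mean in DKD replicate 1 and 0.87 and 0.88 in DKD replicates 2 and 3.

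Tubular injury, interferon response, inflammation and complement lists were higher in DKD, each at a lower level in replicate 1 than in replicates 2 and 3. Tubular injury genes had a median of 1.82, with 18 of 25 higher adjusted over the list alone (camera adjusted p = 8.90e-08; adjusted p = 0.684 with an estimated correlation). Examples were Krt7 (0.70 ± 0.12), Prom1 (0.62 ± 0.14), C3 (2.88 ± 0.55) and the fibrinogen chain Fgg (3.21 ± 0.56). Fgg and C3 are also made in liver, and Fgg was at 119 CPM in DKD replicate 1 against 33.2 and 37.5 in the other DKD kidneys. Havcr1, the injury marker KIM-1 and chosen here after its values were seen, was at 1.85 CPM in DKD replicate 1 and at 33.3 and 24.6 CPM in the other DKD kidneys. The list level was 0.53 above the control mean in DKD replicate 1 and 2.16 and 2.21 in the others. Interferon response genes had a median of 1.59, with 15 of 26 higher adjusted over the list alone (camera adjusted p = 1.24e-08; adjusted p = 0.762 with an estimated correlation), such as Isg15 (2.42 ± 0.40), Ifit3 (1.55 ± 0.27) and Usp18 (2.16 ± 0.42). Their level was 0.76 in DKD replicate 1 and 1.94 and 1.85 in the others. Inflammation genes had a median of 0.97, with 1 of 25 higher adjusted over the list alone, Cxcl9 (2.07 ± 0.40). The camera adjusted p was 0.00012, and 0.797 with an estimated correlation. The list level of DKD replicate 1 was 0.05, beside 1.32 and 1.28 in the others. Over all genes, edgeR without DKD replicate 1 called 14 inflammation genes higher and weighted limma-voom called 10. Complement and coagulation genes had a median of 1.05, with 10 higher and 2 lower of 23 adjusted over the list alone (camera adjusted p = 0.00403; adjusted p = 0.684 with an estimated correlation). C1ra (0.85 ± 0.14) and C1s1 (1.35 ± 0.23) were higher and Cfb (-0.63 ± 0.10) lower, and the list was not called without control replicate 1 (adjusted p = 0.0510). Its level was 0.41 in DKD replicate 1 and 0.77 and 1.15 in the others.

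Macrophage and myeloid genes had a median of 1.10, with 0 of 26 past the threshold adjusted over the list alone (camera adjusted p = 0.0109, and 0.852 with an estimated correlation). That count rested on DKD replicate 1: without it, edgeR called 19 of these genes higher over all genes. Cd68 differed by 1.63 ± 0.42 and Mrc1 by 1.64 ± 0.44 (log2, SE). The list level was -0.47 in DKD replicate 1 and 1.43 and 1.67 in the other DKD kidneys. Without control replicate 1, DKD replicate 2 or DKD replicate 3 the list was not called (adjusted p = 0.108, 0.115 and 0.218), nor with library size alone (0.148). T and NK cell genes had a median of 1.25, with 4 of 19 higher adjusted over the list alone (camera adjusted p = 0.00557, and 0.821 with an estimated correlation). Without DKD replicate 1, edgeR called 13 of these genes higher over all genes. Their level was -0.24 in DKD replicate 1, and the call was lost without control replicate 1 (adjusted p = 0.0510), without DKD replicate 3 (0.0703) and with library size alone (0.0999). Cd8a differed by 1.10 ± 0.25 and Cd3d by 2.12 ± 0.60. The lists of neutrophils (median -0.12) and of B and plasma cells (median 1.40) were not called. The neutrophil level was -1.28, -0.23 and 0.99 in DKD replicates 1 to 3. That of B and plasma cells was -0.90 in DKD replicate 1, and 2.31 and 1.57 in the others.

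Proximal tubule genes were lower in DKD. Of 31 genes 25 had a lower fitted level, and 12 fell and 1 rose adjusted over the list alone (median -0.47; camera adjusted p = 4.70e-08; adjusted p = 0.684 with an estimated correlation). Cyp4b1 (-1.08 ± 0.19) and Cyp2e1 (-1.33 ± 0.25) encode cytochrome P450 enzymes, Hnf4a (-0.66 ± 0.13) a transcription factor of the proximal tubule, and Slc27a2 (-0.60 ± 0.16) a fatty acid transporter. The list level was -0.22 in DKD replicate 1 and -0.75 and -0.71 in the others. Genes higher in male than in female kidneys had a median of -0.55, with 4 of 14 lower adjusted over the list alone (camera adjusted p = 0.000813; adjusted p = 0.684 with an estimated correlation). Among them Cyp2j13 differed by -1.14 ± 0.22. Several genes, Cyp4b1 and Cyp2e1 among them, stand in both the male-biased and the proximal tubule list, so the results for these lists overlap. The level of the male-biased list was -0.09 in DKD replicate 1, inside the controls (-0.13 to 0.18), beside -0.90 and -1.08 in the others. DKD replicate 1 also held hepatocyte transcripts. Whether liver RNA raised its levels of the male-biased and proximal tubule lists was not tested. Nuclear genes of oxidative phosphorylation had a median of -0.24, with 36 of 37 lower in fitted level and 0 past the threshold adjusted over the list alone (camera adjusted p = 9.80e-06, and 0.821 with an estimated correlation). Over all genes, edgeR without DKD replicate 1 called 6 of them lower and weighted limma-voom called 7. Sdha (-0.33 ± 0.11) and Sdhb (-0.45 ± 0.16) are subunits of succinate dehydrogenase. That list was not called without control replicate 1 (adjusted p = 0.0510), and with library size alone, which moved the median of all genes by 0.15, its median was -0.09. Its level was -0.06 in DKD replicate 1, above those of control replicates 2 and 3 (-0.11 and -0.14), while control replicate 1 was at 0.24 and the other DKD kidneys at -0.26 and -0.33.

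Collecting duct genes had a median of 0.28, with 2 higher and 1 lower of 20 adjusted over the list alone (camera adjusted p = 0.0312; adjusted p = 0.797 with an estimated correlation). The proton pump subunit Atp6v0d2 differed by 0.62 ± 0.11 and the water channel Aqp4 by -0.97 ± 0.24. The call was lost without control replicate 2 (adjusted p = 0.0510), control replicate 3 (0.260), DKD replicate 1 (0.158) and DKD replicate 2 (0.115). Immediate early and heat shock genes had a median of 0.49, with 0 of 23 past the threshold adjusted over the list alone (camera adjusted p = 0.0452; adjusted p = 0.852 with an estimated correlation), including Junb (1.04 ± 0.27) and Atf3 (1.73 ± 0.64). That call was lost without control replicate 2 (adjusted p = 0.381), control replicate 3 (0.208), DKD replicate 2 (0.0971) and DKD replicate 3 (0.422), with the replicate block (0.0591), with library size alone (0.197) and with upper quartile factors (0.0517). Its level was -0.26 in DKD replicate 1, beside 0.68 and 1.05 in the other DKD kidneys and 0.38, -0.25 and -0.04 in the controls.

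**Figure D2:**
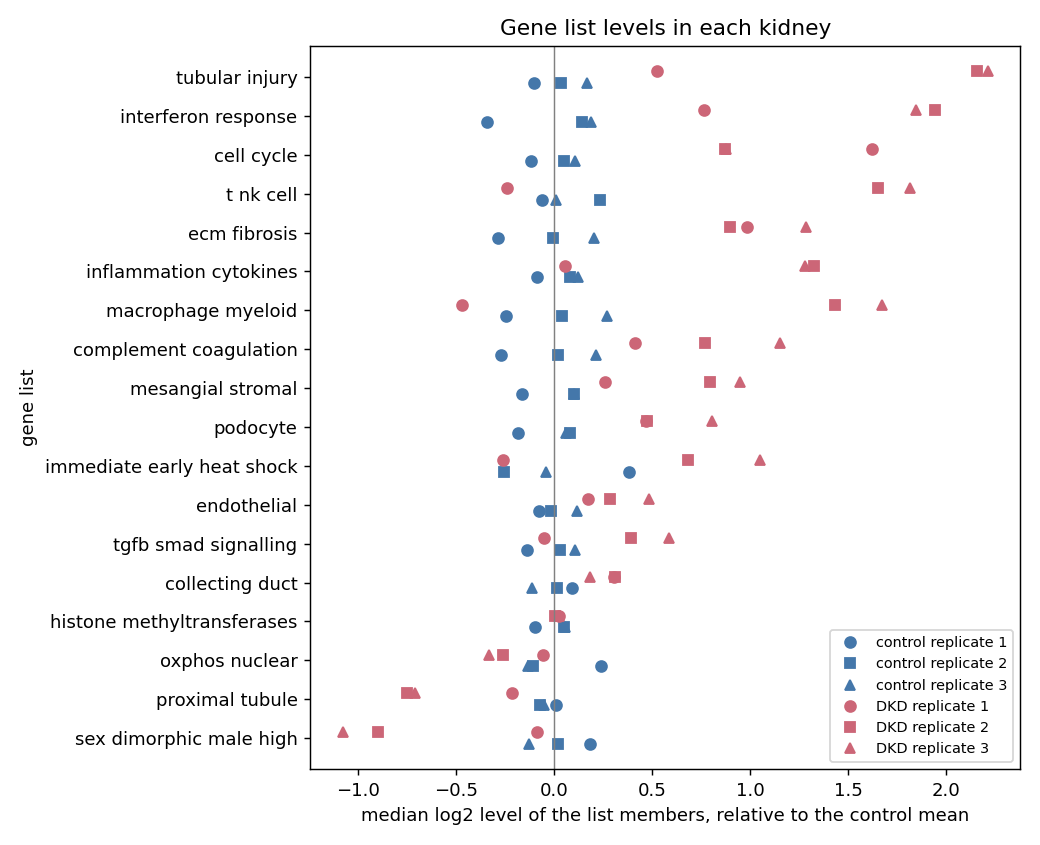
Level in each kidney of the 17 gene lists that camera set apart and of the histone methyltransferases (horizontal axis, median log2 level of the list's members relative to the control mean). Blue is control, red is DKD, and marker shape gives the replicate number. DKD replicate 1 lies at -0.47 for macrophage genes and at 0.53 for tubular injury, below the other DKD kidneys, and at 1.62 for cell cycle genes, above them.

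Among the lists that camera did not set apart, the camera adjusted p was 0.644 for histone demethylases, 0.738 for the loop of Henle, 0.102 for the distal tubule, 0.671 for neutrophils, 0.213 for B and plasma cells, 0.736 for fatty acid oxidation, 0.236 for lipogenesis and cholesterol, 0.867 for glycolysis and 0.867 for gluconeogenesis and glucose transport. It was 0.139 for mitochondrially encoded genes, 0.801 for NRF2 and antioxidant genes, 0.867 for ER stress, 0.527 for the circadian clock, 0.697 for genes higher in female kidneys and 0.738 for renin and angiotensin. Markers of other tissues gave 0.644 for adipocytes, 0.368 for adrenal, 0.738 for skeletal muscle and 0.738 for erythroid cells, but 6 of 13 adipocyte, 2 of 12 adrenal and 3 of 12 skeletal muscle genes were tested, and 7 of 14 neutrophil genes. Within glycolysis, 2 of 20 genes rose adjusted over the list alone: Pfkfb3 (1.29 ± 0.17) and Pdk1 (0.71 ± 0.11), both regulators of the pathway. Adjusted in the same way, 1 B and plasma cell gene rose and 1 of the 2 tested adrenal genes fell. B and plasma cell genes were called without DKD replicate 1 (adjusted p = 1.64e-05), as were lipogenesis and cholesterol (0.0488) and adipocyte genes (0.0467). With quality weights B and plasma cell genes (0.0119) and lipogenesis and cholesterol (0.0315) were called, and adipocyte genes without a low count filter (0.0210). The adrenal list, with 1 tested gene higher and 1 lower in fitted level, was called without control replicate 1 (0.0340) and without DKD replicate 3 (0.0375), and the distal tubule list without control replicate 2 (0.0349).

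Weighted limma-voom, in which DKD replicate 1 had a weight of 0.302 and control replicate 1 of 0.502 against 1.18 to 2.07 for the others, gave the genes with the largest changes. None of these 24 genes was called by edgeR, where their adjusted p ran from 0.103 to 0.560. Those higher in DKD were Ttr, Igfbp2, Clic6, Zfp125, Rdh9, Saa4, Ugt2b35, Xlr4b, Mettl7a2, Sptssb, Slc39a4 and Psca. Igfbp2, which binds insulin-like growth factors, was at 0.539, 0.152 and 0.0564 CPM in control and 20.1, 22.8 and 43.2 CPM in DKD kidneys (adjusted p = 0.0185 with weighted limma-voom, 0.103 with edgeR). Psca was at 0.992 ± 0.656 CPM in control and 22.5 ± 14.5 CPM in DKD kidneys (SD, n = 3). Ttr, the thyroid hormone carrier transthyretin, was at 89.3 CPM in control replicate 1 but 0.485 and 0.339 CPM in the other controls, and at 179.7, 181 and 257 CPM in DKD (log2 8.00 with weighted limma-voom, 2.78 ± 1.98 with edgeR; adjusted p = 0.480 with edgeR). Control replicate 1 also lay near the DKD kidneys for Mettl7a2, at 87.2 CPM against 0.970 and 1.54 CPM in the other controls and 90.4, 105 and 145 CPM in DKD (log2 5.82 with weighted limma-voom, 1.93 ± 1.65 with edgeR; adjusted p = 0.560 with edgeR). Zfp125 was at 0.976, 0.0152 and 0.0141 CPM in control and 1.81, 3.65 and 3.75 CPM in DKD kidneys (adjusted p = 0.266 with edgeR). Saa4 and Ugt2b35 had no count in any control and were highest in DKD replicate 1, at 10.8 and 5.35 CPM. That library also held hepatocyte transcripts, so liver RNA may have added to its values of the genes higher in DKD, Ttr included. The naming rule required no overlap between groups, so such RNA could also affect which genes are named. This was not tested. Those lower in DKD were BC002163, Rpsa-ps10, Trdn, C4a, Cyp4a12a, Cyp2d12, Dnase1, Tpm3-rs7, Pla2g2c, Azgp1, Rpl15-ps2 and Hsd3b2. Dnase1, a secreted nuclease, was at 1970.1, 2225 and 2205 CPM in control and 826, 357 and 222 CPM in DKD kidneys, and Azgp1 differed by -2.41 ± 0.38 (log2, SE). Others of these genes lay near the controls in DKD replicate 1. BC002163 was at 19.7, 26.2 and 24.4 CPM in control kidneys and 14.9 CPM in DKD replicate 1, against 0.844 and 0.742 CPM in the other DKD kidneys (log2 -4.58 with weighted limma-voom, -2.09 ± 1.22 with edgeR; adjusted p = 0.394 with edgeR). Rpsa-ps10 was at 224, 291 and 288 CPM in control and 179, 13.5 and 13.5 CPM in DKD kidneys (log2 -4.07 with weighted limma-voom, -1.96 ± 1.11 with edgeR), and Hsd3b2 at 360.4, 468 and 615 CPM and at 299.6, 73.0 and 77.8 CPM. Values of Rpsa-ps10, Rpl15-ps2, Tpm3-rs7, C4a, Cyp4a12a and Mettl7a2 are uncertain, since near-identical genes can share their reads.

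**Figure D3:**
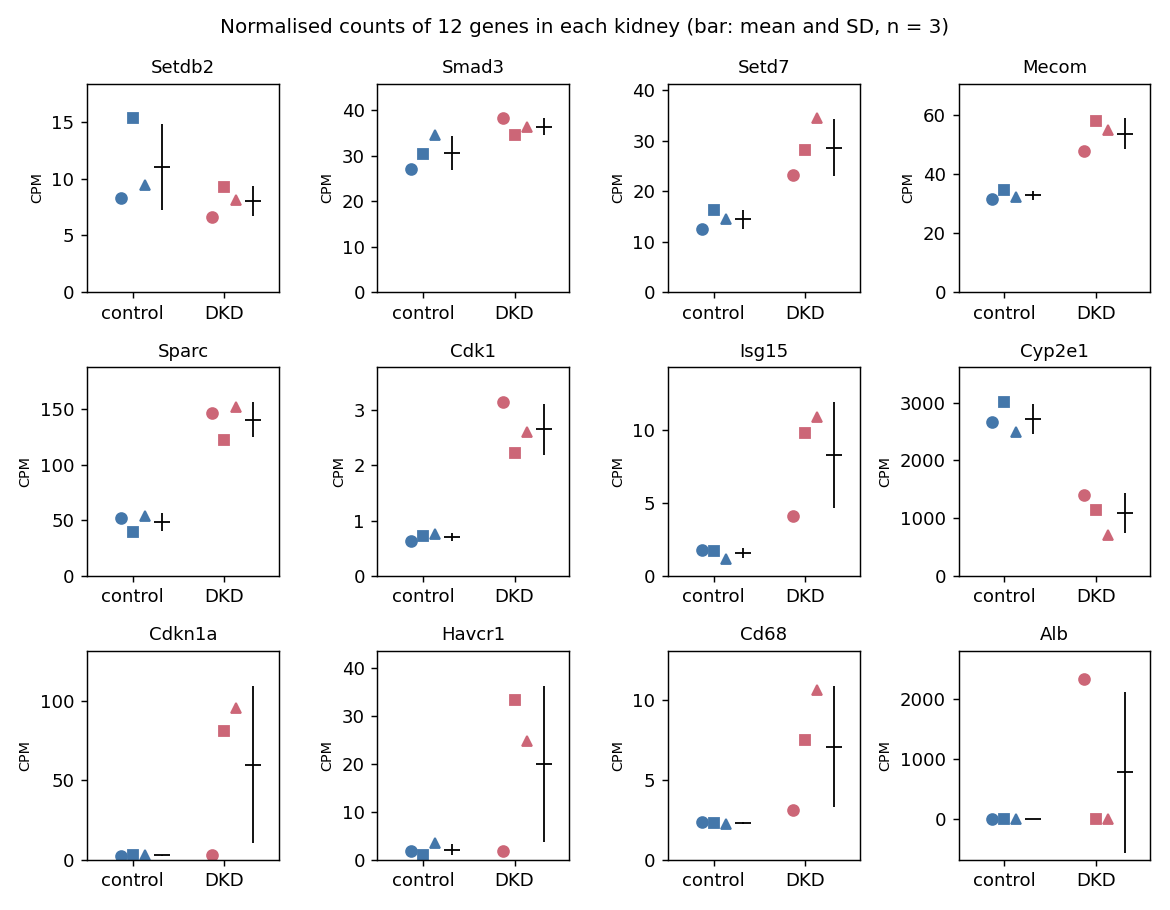
Normalised counts (vertical axes, CPM) of 12 genes in each kidney, with blue for control, red for DKD, marker shape by replicate number, and the mean and SD of 3 kidneys beside the points. DKD replicate 1 sits with the other DKD kidneys for Sparc and Cdk1, near the controls for Cdkn1a and Havcr1, and alone for Alb at 2321 CPM.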

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

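Alternatives chosen only after the data were seen are limma-voom without weights, the weighted and DESeq2 fits on fewer libraries, camera with quality weights, and 2 scalings of the lists. The edgeR count of 0 genes, 0 higher and 0 lower was the same with RLE, upper quartile or no scaling factors, the strict filter, the 50 most counted genes left out, glmTreat, a fit that was not robust, and the replicate block (0 genes). Equal replicate numbers share no stated animal or day, and the deviations of same-numbered libraries correlated by 0.03, 0.02 and 0.03, although every library correlated best with its own number, a hint from the data and not from the design; under the block 16 other lists were called. Without a filter 4 genes were called (3 higher, 1 lower), with unweighted limma-voom 1 (lower), with DESeq2 1749 (1195 higher, 554 lower) and with weighted limma-voom 3401 (1907 higher, 1494 lower). DESeq2 gave no adjusted p for 2323 genes, and shared 1589 calls in the same direction with the weighted fit. Leaving out each library in turn gave 0 to 3101 genes (0 to 1933 higher, 0 to 1168 lower) with edgeR, the highest without DKD replicate 1, of which 2358 were shared with the weighted fit of all libraries. The weighted fit gave 0 to 4877 genes (0 to 2962 higher, 0 to 1915 lower), with 2012 (1013 higher, 999 lower) without control replicate 1, and DESeq2 gave 4658 (2630 higher, 2028 lower) without DKD replicate 1. Histone methyltransferases called went from 0 to 3 with DESeq2, 5 with weights, 0 to 4 with edgeR and each library left out, 0 to 5 with weights (3 without control replicate 1), and 6 with DESeq2 without DKD replicate 1. The cause of the differences between tools was not tested. Their list test kept an adjusted p of 0.489 or more in every alternative, 0.501 to 0.996 with a library left out, and turned to lower with quality weights (0.915). The count of other lists was 13 to 19 except with an estimated correlation (0) and fry (1). Directions turned for lists that were not called before or after: glycolysis (adjusted p = 0.931 with library size alone, 0.891 with weights, 0.738 with fry, 0.604 to 0.969 with each library left out), histone demethylases (0.876 with library size alone), NRF2 genes (0.915 with weights, 0.815 with fry, 0.541 to 0.973), gluconeogenesis (0.822 with fry, 0.637 to 0.965), neutrophils (0.858 without a filter, 0.0703 to 0.773), the loop of Henle (0.539 to 0.911), erythroid cells (0.292 to 0.989), ER stress (0.539 to 0.897), fatty acid oxidation (0.251 to 0.893) and renin and angiotensin (0.145 to 0.968), where the ranges are over each library left out. Of 81 single genes refitted (75 with the strict filter, 78 without the 50 most counted genes), only Alb changed direction, from higher to lower, without DKD replicate 1 (log2 -0.70 with weights, -0.69 with DESeq2; edgeR -0.68 to 6.45 over each library left out), as that library holds nearly all of its counts in DKD. Depth limits what can be said of genes with no count in a library, which could still be present at 0.0353 to 0.0505 CPM; no shallower depth was tried.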

Other observations

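Tests chosen only after their result was seen were those of dilution, of a control kidney under a DKD label, of the neighbours of Nnt, of the proximal tubule share, of the sex of the animals and of the splits for gene and methyltransferase counts. Cdkn1a, Eda2r, Phlda3 and Psrc1, which p53 is known to induce, were far higher in DKD replicates 2 and 3 than in the other libraries. Cdkn1a, which halts the cell cycle, was at 2.10 to 2.97 CPM in controls, 3.17 CPM in DKD replicate 1, and 81.1 and 95.6 CPM in DKD replicates 2 and 3. Eda2r was at 0.250 CPM in DKD replicate 1 and at 12.2 and 11.4 CPM in the other DKD kidneys. A hypothesis is that p53 target genes were higher as a group. Of 25 other p53 targets, listed before their values were looked at, 20 had a higher fitted level in DKD over all 6 libraries (median 0.46; camera adjusted p = 0.0138 over 38 lists), which is in line with it. The call was lost with an estimated correlation (adjusted p = 0.767), and the list level was -0.03 in DKD replicate 1 against 0.61 and 0.61 in the others.

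DKD replicate 1 held hepatocyte transcripts and lacked much of the injury and immune gene levels of the other DKD kidneys. Of 36 hepatocyte genes not looked at before, 29 (80.6%) were more than 4 times higher there than in every other library, just past the 80% set beforehand; 11 of the 36 have a mean of 1 CPM or more in control kidneys and 0 stand in another list. Serpina3k was at 388 CPM and Ahsg at 376 CPM there, with no count in any other library, so liver RNA in that library is a candidate source. Dilution by such RNA is argued against as the cause of the lower injury level: the median injury gene lay -1.33 from the other DKD kidneys (log2), while the median of 77 nephron segment genes lay 0.09 from the control mean. TMM scaling takes out an even dilution, so the nephron segment value alone could not show one. The TMM factor was 0.986 in DKD replicate 1, against 0.917 to 1.10 in the other libraries, so the scaling hid no large dilution. The evidence on a control kidney like these 3 under a DKD label was mixed. The median share that this library showed of the shift of the other DKD kidneys exceeded that of each left-out control on the same genes. The excess was 0.117, 0.189 and 0.148, the first only just above the range of 0.113 between controls. Hepatocyte genes were not removed for this. The cell cycle and matrix levels of this library lay 1.51 and 0.78 above the highest control (log2). The controls themselves ranged over 0.23 and 0.49. These values argue against such a kidney, but the test and its lists were chosen after the levels were seen. This library lay below every control for macrophage genes (-0.47) and for T and NK cell genes (-0.24). For TGF-beta genes (-0.05) it lay among the controls. The question is therefore not decided, and a control kidney holding liver RNA was not tested. A kidney from outside these groups and a milder disease stay open, untested.

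Control replicate 1 with DKD replicates 2 and 3, against the other libraries, gave 3189 genes in weighted limma-voom, beside 3401 for the real groups, and 7 in edgeR, beside 0. Of those 3189 calls 70.6% were made in the same direction by the real groups, in line with the same libraries carrying both weighted fits; the 7 edgeR calls were not compared in this way. Nnt, a mitochondrial transhydrogenase, followed that split: one of its 2 overlapping gene IDs held 159.9, 116 and 124 CPM in these libraries and no count in the others. Genes within 100 tested neighbours of Nnt were 5.10 times as often among the 200 smallest p-values of this split as other genes (6 of 117 neighbours), so a difference in the genetic background of the animals around this gene may contribute. Control replicates 2 and 3, without counts of that ID, and DKD replicates 2 and 3, with them, had the highest weights in the weighted DKD comparison. Among those libraries such a difference cannot be told apart from DKD. Nnt was chosen after its values were seen, and the strain is not given in the labels.

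Proximal tubule and male-biased genes were lower in DKD while several other lists were higher. A lower share of proximal tubule cells would raise the markers of other cell types alike. The podocyte level moved 0.55 ± 0.23 (log2, SE, n = 3) above that of the loop of Henle, 2.40 times its standard error. In DKD replicate 1 the podocyte and loop of Henle levels were 0.47 and 0.22. In control replicate 2 they were 0.08 and -0.15, nearly as far apart. With 3 libraries per group this does not decide whether a lower share is the whole cause. Female animals among the DKD kidneys are argued against by Xist, which was at most 0.00974 of the mean of 4 Y-linked genes in any DKD library. A change within the proximal tubule in DKD stays open as an untested biological explanation.

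The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real groups gave 0 genes with edgeR and the highest other split 7, so all 10 splits gave as many. With weighted limma-voom the real groups gave 3401 genes and the highest other split 3189, and 1 split, the real one, gave as many. For histone methyltransferases the real groups and the highest other split both gave 0, in 10 splits. For gene lists the real groups gave 17 and the highest other split 16. Camera on the methyltransferase list gave an unadjusted value of 0.901 for the real groups and 0.0546 as the smallest of the others, and all 10 splits gave one as small as the real groups.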
